A study of Mus musculus with 8 samples.

How the data were processed

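Messenger RNA of the mouse microglial line BV-2 was measured on 8 single-colour Agilent arrays, 2 for each of 4 groups, treated for 24 h. All 8 arrays lay on 1 slide and were read in 1 scan. Per the file headers, the intensity values of each spot were made by the Agilent Feature Extraction software, which subtracted the background and corrected trends across the array, without any scaling between arrays. The log2 values in the deposited series matrix were made by the authors from these signals, shifted to each array's 75th percentile and centred on each probe's median; both steps were checked by recomputing them. The raw median pixel brightness of spots and of their local background also stood in the scanner files. Mean pixel brightness did not, so the planned normexp background correction, with an offset of 50, used medians, which lack the scanner's trend correction. The number of arrays limits the precision of all values.

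The processed signals were converted to log2, averaged over the repeated spots of a probe that the scanner software had not marked as faulty, and shifted to the array's 75th percentile. Probes were kept if they were well above background on both arrays of at least 1 group, which left 30345 probes. Of the 55681 probes that were not controls, 28026 (50.3%) could be given a symbol through RefSeq and Ensembl transcript names, and these stand for 21154 genes. Others kept the name in the scanner files. For each gene the kept probe with the highest mean over the 8 arrays was used, which gave 22460 genes. Where both arrays of a group lay below background, the fold is given as "at least". It was taken against the array's lowest signal of any probe above background, or against the measured signal where that was higher. This limit is not the probe's own, so "at least" is approximate.

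Group means were fitted with limma (version 3.58.1 in R 4.3.3) over all 8 arrays, with moderated variances (4 residual and 2 prior degrees of freedom). There were 5 comparisons: LPS minus control, HF minus control, LPS+HF minus LPS, LPS+HF minus HF, and the interaction of LPS and HF. A gene passed with a Benjamini-Hochberg adjusted p under 0.05, two-sided, over all genes tested. Lists of genes, 27 in all, were written from general knowledge before the data were examined, and each had at least 5 measured members. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the 27 lists within a comparison, and again with an estimated correlation and with fry. The response to LPS with HF was compared with that without HF as a slope through the origin across genes, and the differences with HF were correlated across genes.

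The genes named follow a rule fixed before the data were examined. It takes, per comparison, the 10 largest rises and 10 largest falls among genes that passed, had separated arrays and an approved-style symbol (5 and 5 for the interaction). It adds up to 4 passed members of each list, or 2 as values where none passed, and always Nos2, Tnf, Il6, Il1b, Ptgs2, Hmox1 and Actb.

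Alternatives fixed before the data were examined were the normexp background correction with quantile normalization, quantile normalization alone, median scaling, the authors' matrix, no filter on dim probes, probes above background on all arrays, the mean over a gene's probes, each probe on its own, a trended and robust variance, a 2-fold threshold, the replicate number as a block, only the arrays compared, and leaving out each array in turn. When an array was left out, the lone array of its group was assumed to vary like the others. Alternatives added after the data were seen were a spatial correction, its combination with the replicate block, leaving out both arrays marked by the scanner's quality report, and array weights. The spatial correction subtracted each array's local deviation from the mean of the arrays inside the scanner's quality range, in windows of 30 rows and 15 columns of spots, and masked spots where the signal before the scanner's trend correction was dimmed more than 4-fold. A block for slide or scan was not run, since there was 1 of each. The fit was tested on simulated data with 200 changed genes in each of 20 draws and 1 spread ratio per group for all genes. The real number of changed genes is not known, so the simulated shares of false calls need not carry over. The list test was tried on lists of 25 genes. A shift of 1 log2 was found in 20 of 20 draws, and 1 of 520 unshifted lists was called. Data were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.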

Results

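The study measured messenger RNA in BV-2 cells, a mouse microglial line immortalised with a retrovirus and used in place of the brain's resident macrophages. Cells were left untreated (control) or received lipopolysaccharide (LPS, 1 µg/mL), a hexane fraction of the mushroom Amauroderma rugosum (HF, 100 µg/mL), or both (LPS+HF), for 24 h. LPS is a component of the outer membrane of Gram-negative bacteria and is sensed through Toll-like receptor 4. Each of the 4 groups had 2 arrays, 8 in all, each hybridised with RNA labelled with the dye Cy3. The study calls them biological replicates, but it is not known whether the 2 arrays of a group came from independent cultures, so the SE and adjusted p may not cover the variation between cultures. The number of arrays limits the precision of every value below. The 75th percentile of spot brightness lay between 247 and 286 on the arrays without HF and between 346 and 527 on those with HF, before each array was scaled to it. Of the 55681 probes, 47.8% to 55.0% per array were well above background. Tests covered 22460 genes, 13802 of them with a gene symbol.

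Repeated probes gave uneven signals on control replicate 1. The coefficient of variation of its repeated probes was 48.9%, against 3.77% to 8.06% on the other 7 arrays, and the scanner's quality report marked it for evaluation. The same mark stood on HF replicate 1, whose coefficient of variation was 8.06%. The scanner software also marked the spot grid of control replicate 1, and of no other array, as not good. The SD of the difference between replicate arrays over the genes was 0.99 log2 for control, 0.28 for LPS, 0.49 for HF and 0.34 for LPS+HF. Each SE below pools the spread over all 8 arrays, not only the arrays compared. Over the genes, it is thus too narrow for comparisons with control and too wide for those without. With only the arrays compared, 67 genes passed in LPS minus control, 0 in HF minus control and 7397 in LPS+HF minus LPS. A spatial correction, chosen after the unevenness of control replicate 1 was seen, removed each array's local deviation and masked 16.3% of that array's spots. The control SD was then 0.43, over the 18986 genes left to compare. Named genes whose spot was masked on control replicate 1 are given with their value or adjusted p after the correction. All arrays with HF lay in 1 row of the slide and all arrays without HF in the other, so slide row and HF cannot be told apart. Arrays with LPS all lay in slide columns 3 and 4, and arrays without LPS in columns 1 and 2. Slide column and LPS therefore cannot be told apart either. Quantile normalization moved the median of all genes from -0.08 to 0.04 log2 in LPS minus control and from -0.07 to 0.04 in HF minus control, but both scalings fix the centre of each array, so these medians do not test the scaling.

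The series title asks how HF modulates LPS-stimulated cells, which LPS+HF minus LPS addresses. Of 43 measured interferon-stimulated genes, 26 fell with HF and 17 did not pass; the list passed with the preset correlation (adjusted p = 1.8e-21), but not with an estimated correlation (adjusted p = 0.21). Isg15, a ubiquitin-like protein induced by interferon, fell 11.6-fold (log2 -3.53 ± 0.29 SE, 2 arrays per group, adjusted p = 0.0088). Ifit3, which binds viral RNA together with its relatives, fell 12.7-fold (log2 -3.67 ± 0.28, adjusted p = 0.008), with log2 -3.75 after the spatial correction. Inflammatory mediators split: Il6, the cytokine interleukin 6, fell 8.04-fold (log2 -3.01 ± 0.22, adjusted p = 0.008), while Tnf, tumour necrosis factor, rose 2.35-fold (log2 1.23 ± 0.13, adjusted p = 0.011).

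In that comparison 1404 genes passed, 672 higher and 732 lower with HF. The split was 751 higher and 693 lower under median scaling, 3323 and 3139 after the spatial correction, 68 and 164 with the normexp background correction, and 51 and 117 without the filter on dim probes. Of the inflammatory genes followed throughout, Il1b, the cytokine interleukin 1 beta, fell by 2.33 ± 0.25 log2 (adjusted p = 0.012). Nos2, the inducible nitric oxide synthase, fell 2.63-fold (log2 -1.39 ± 0.19, adjusted p = 0.02). Hmox1, a haem-degrading enzyme of the antioxidant response, fell 3.26-fold (log2 -1.70 ± 0.17, adjusted p = 0.011), with log2 -1.76 after the spatial correction. Ptgs2, the inducible cyclooxygenase, did not pass (log2 -0.06, adjusted p = 0.9), nor did Actb, cytoskeletal actin (log2 -0.33, adjusted p = 0.39; 0.04 under quantile normalization).

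The largest falls with HF in LPS-stimulated cells were in genes of several kinds. Ifi209, an interferon-inducible DNA sensor family member, fell at least 36.6-fold, since neither LPS+HF array was above background. Its spot was masked on control replicate 1 and HF replicate 1, and it passed after the correction too (adjusted p = 0.00072). Macc1, a transcriptional regulator studied in tumour metastasis, fell at least 7.91-fold. Slamf7, a receptor of activated macrophages, fell 23.9-fold (log2 -4.58 ± 0.35). Prss46, a serine protease, fell 21.3-fold and Msr1, a scavenger receptor, fell 19.8-fold. Ifi211, another member of the DNA sensor family, fell 16.5-fold. Slfn4, a myeloid gene induced by interferon, fell at least 4.62-fold, and Mirt2, a long non-coding RNA induced by LPS, at least 4.28-fold. Bsph2, a binder of sperm protein, fell at least 4.97-fold and Car6, a secreted carbonic anhydrase, at least 3.85-fold.

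Rises with HF in LPS-stimulated cells were smaller. Sfpq, a splicing factor, rose 7.84-fold (log2 2.97 ± 0.14, adjusted p = 0.0044). Btg2, an antiproliferative gene, rose 6.89-fold and Egr2, a transcription factor of myeloid cells, rose 6.44-fold. Lbp, the LPS-binding protein, rose 5.82-fold. Cxcl2, a neutrophil chemoattractant, rose 6.46-fold (log2 2.69 ± 0.26, adjusted p = 0.011). Nebl, a muscle actin-binding protein that was dim on both LPS arrays, rose at least 2.53-fold, or 1.25-fold with LPS+HF replicate 2 alone, and passed in 2 of the 8 fits without 1 array. Pianp, a neuronal receptor ligand, rose at least 2.38-fold, Vmn1r45, a pheromone receptor, at least 2.11-fold, and Armc3, a cilium-related gene, at least 1.76-fold. The spots of these last 3 genes and of Ttc23l, another cilium-related gene with a 5.74-fold rise, were masked on control replicate 1. After the correction Pianp, Vmn1r45 and Armc3 also passed (adjusted p = 0.00064, 0.0031 and 0.0011), and Ttc23l had a log2 of 2.46; its value ranged from 1.73 to 3.31 when 1 array was left out.

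**Figure D1:**
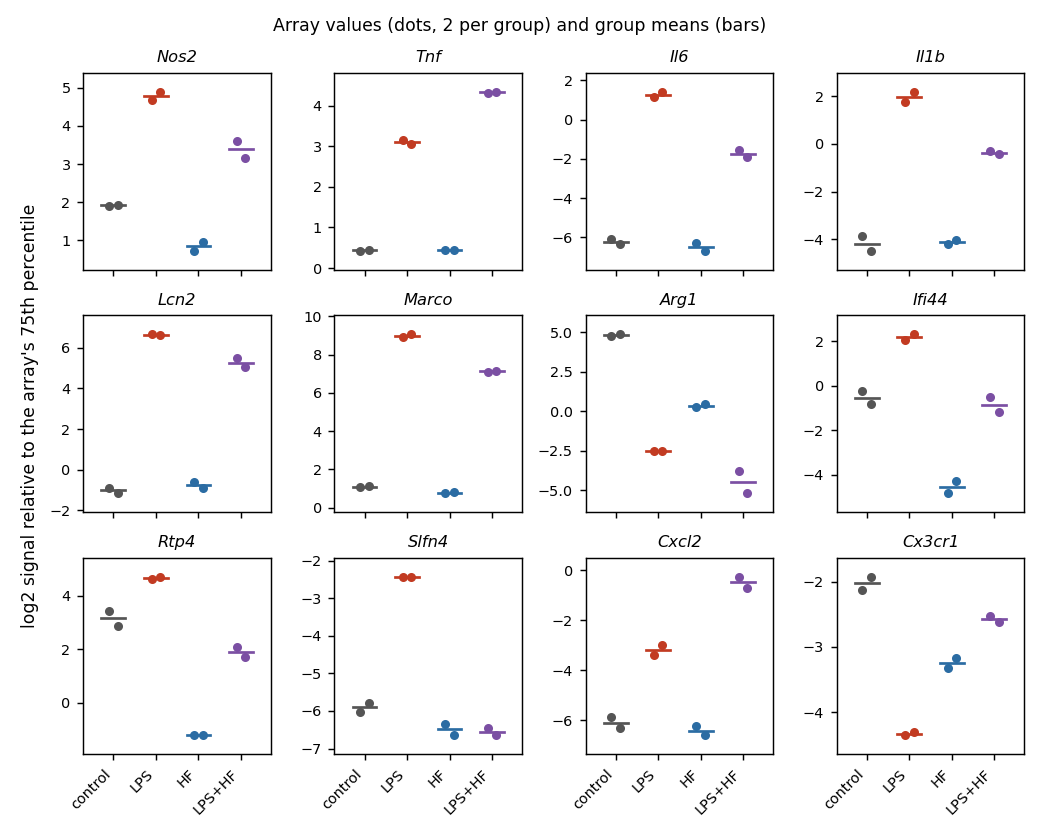
Signals of 12 genes on the 8 arrays (dots) with group means (bars), as log2 relative to each array's 75th percentile. Il6 and Il1b lie lower in LPS+HF than in LPS, by 3.01 and 2.33 log2, while Tnf and Cxcl2 lie higher, by 1.23 and 2.69.

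Interferon-stimulated genes formed the list with the largest median in LPS+HF minus LPS. Of 43 measured members, 26 fell, none rose and 17 did not pass; adjusted over the list alone, 35 fell. The list's median was -1.86 (adjusted p = 1.8e-21; adjusted p = 0.21 with an estimated correlation). Ifi44, an interferon-induced antiviral gene, fell 8.07-fold, and Isg20, an interferon-induced exonuclease, fell 8.09-fold, with log2 -3.09 after the spatial correction. Mitosis genes moved the other way: 12 of 32 rose, 20 did not pass and, adjusted over the list alone, 23 rose. Their median was 1.01 (adjusted p = 5.1e-17; adjusted p = 0.21 with an estimated correlation). Ccnb2, a mitotic cyclin, rose 3.33-fold, Kif20a, a kinesin of cell division, 3.31-fold, Cdc20, an activator of mitotic exit, 2.93-fold, and Ube2c, its partner ubiquitin-conjugating enzyme, 2.72-fold.

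Cytokines and inflammatory mediators went both ways with HF in LPS-stimulated cells. Of 22 measured members, 9 fell, 2 rose and 11 did not pass; adjusted over the list alone, 11 fell and 4 rose. The median was -0.40 (adjusted p = 0.025; adjusted p = 0.45 with an estimated correlation). The list did not pass after the spatial correction (median -0.35, adjusted p = 0.063), without either control array (adjusted p = 0.1) or without LPS+HF replicate 2 (median -0.31, adjusted p = 0.13). Nor did it without the filter on dim probes (median -0.19) or with probes above background on all arrays (median -0.08). With the mean over a gene's probes the list passed (median -0.63, adjusted p = 0.0084 in camera). Il1rn, which encodes the natural antagonist of interleukin 1, fell 7.89-fold, and Acod1, which makes itaconate in activated macrophages, fell 2.70-fold. Among 14 chemokines, 5 fell, 3 rose and 6 did not pass; adjusted over the list alone, 6 fell and 3 rose. The chemokine list did not pass as a whole (median -0.34, adjusted p = 0.23). Ccl5, which attracts T cells, fell 8.50-fold, Ccl12, a monocyte attractant, 6.84-fold, and Ccl9, a macrophage chemokine, 4.13-fold.

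The cholesterol synthesis list was lower with HF in cells with LPS. Of 25 measured members of that list, 8 fell, none rose and 17 did not pass; adjusted over the list alone, 10 fell and 1 rose. The median was -0.68 (adjusted p = 0.00025; adjusted p = 0.29 with an estimated correlation). Mvd, Fdps and Fdft1, enzymes of the mevalonate and squalene steps, fell 2.89-fold, 2.24-fold and 2.07-fold. Lss, which cyclises squalene epoxide, fell 2.33-fold, with log2 -1.30 after the spatial correction. Lysosome and autophagy genes had a median of -0.42 (adjusted p = 0.00025; adjusted p = 0.29 with an estimated correlation). Of 30 measured, 3 fell and 27 did not pass, and 9 fell when adjusted over the list alone. Atp6v0d2, a subunit of the proton pump, fell 5.54-fold, while Psap, a precursor of lipid-degrading cofactors, and Ctsd, a protease, fell 1.88-fold and 1.78-fold.

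Some stress genes were lower with HF in cells with LPS. In the integrated stress response list, 4 of 22 fell, none rose and 18 did not pass, or 7 fell adjusted over the list alone (median -0.27, adjusted p = 0.021; adjusted p = 0.42 with an estimated correlation). This list did not pass after the spatial correction (median -0.24, adjusted p = 0.063) or without either control array (adjusted p = 0.069). Ddit3, a transcription factor of stress-induced death, fell 13.2-fold (log2 -3.73 ± 0.22, adjusted p = 0.0057). Trib3, a pseudokinase it induces, fell 4.78-fold and Atf3, a stress transcription factor, 2.22-fold. In the NRF2 and antioxidant list 3 of 31 fell and 28 did not pass; adjusted over the list alone, 4 fell and 1 rose (median -0.30, adjusted p = 0.045; adjusted p = 0.29 with an estimated correlation). It did not pass with the mean over a gene's probes or the replicate block (adjusted p = 0.059 and 0.054 in camera). Nor did it without LPS replicate 2 (median -0.29), either HF array (-0.30) or LPS+HF replicate 2 (-0.24). Without both arrays marked for evaluation it did not pass either (median -0.30). Its median was -0.16 with the normexp background correction. Esd, an esterase, fell 2.13-fold and Prdx1, a peroxidase, 1.76-fold. Antigen presentation genes had a median of -0.41 (adjusted p = 0.033; adjusted p = 0.45 with an estimated correlation), with 2 of 20 lower and 18 not passed, or 3 lower and 1 higher adjusted over the list alone. They did not pass with the mean over a gene's probes (adjusted p = 0.081 in camera). Nor did they without LPS replicate 1 (median -0.40) or LPS+HF replicate 2 (median -0.33). The peptide transporter genes Tap1 and Tap2 fell 2.63-fold and 1.77-fold.

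The glycolysis and hypoxia list was higher with HF in cells with LPS. Of 26 measured, 6 rose, 1 fell and 19 did not pass; adjusted over the list alone, 8 rose and 2 fell. The median was 0.35 (adjusted p = 0.0063; adjusted p = 0.21 with an estimated correlation). Egln1, an oxygen sensor, rose 2.90-fold, Pfkl, a phosphofructokinase, 2.68-fold, Pdk1, which diverts pyruvate from mitochondria, 2.58-fold, and Ndrg1, a hypoxia-responsive gene, 1.87-fold. DNA replication genes had a median of 0.47 (adjusted p = 6.6e-05; adjusted p = 0.29 with an estimated correlation), with 1 of 31 higher, 30 not passed and 0 adjusted over the list alone. That gene was Rrm2, a subunit of ribonucleotide reductase, at log2 0.75 and 0.71 after the spatial correction.

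The other 17 lists did not pass in LPS+HF minus LPS. Single members did: Cx3cr1, the fractalkine receptor of microglia, rose at least 3.08-fold, and P2ry12, a purine receptor of resting microglia, fell at least 2.06-fold. Nfkbia, an inhibitor of NF-kB, rose 2.33-fold and Traf1, a receptor adaptor, fell 2.45-fold. Fabp4, a lipid carrier, fell 4.11-fold.

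Without LPS replicate 1 or 2, 0 genes passed in limma for LPS+HF minus LPS, with 2981 and 3115 at an unadjusted p under 0.05. The count was 6567 without either control array, 309 without either HF array, and 52 and 7 without LPS+HF replicate 1 and 2. None of the 82 named genes that passed changed direction in these fits. In simulated data with the group spreads of these arrays, 65.0% of 4-fold and 9.15% of 2-fold changes were found for this comparison over 22443 genes, with 0.135% false calls.

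**Figure D2:**
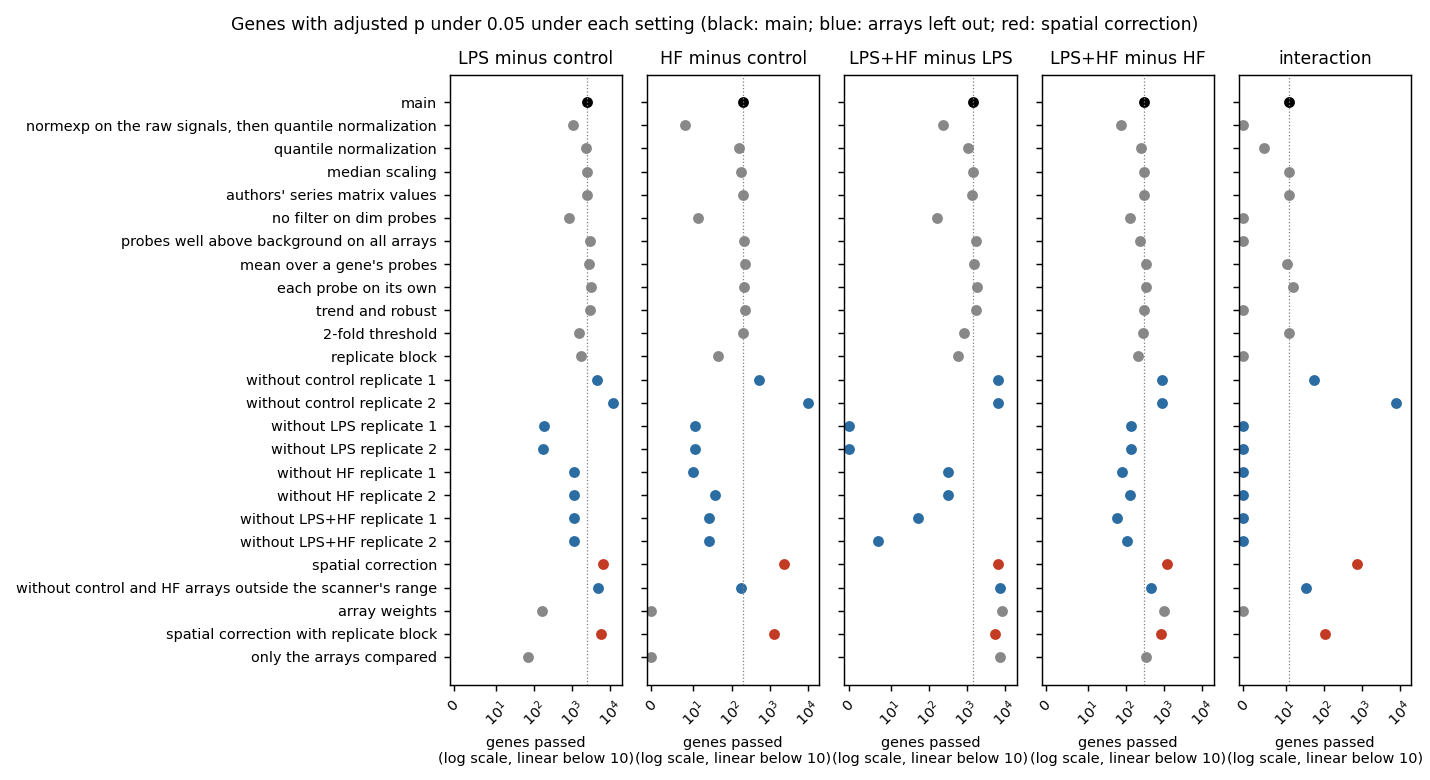
Genes with adjusted p under 0.05 in each comparison under each setting, on a log axis that is linear below 10. The LPS+HF minus LPS count goes from 1404 to 0 when an LPS array is left out and to 6567 when a control array is.

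LPS minus control asked what LPS did to cells without HF. Marco, a scavenger receptor for bacteria, rose 239-fold (log2 7.90 ± 0.13 SE, 2 arrays per group, adjusted p = 2.8e-05). Lcn2, which sequesters bacterial iron carriers, rose 202-fold (log2 7.66 ± 0.20, adjusted p = 0.00012). Il6 was below background on both control arrays and rose at least 56.3-fold (adjusted p = 0.00016). Arg1, an arginase typical of alternatively activated macrophages, fell 159-fold (log2 -7.31 ± 0.42, adjusted p = 0.0011).

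In all, 2502 genes passed for LPS minus control, 1078 higher and 1424 lower. The split was 1182 higher and 1076 lower under quantile normalization, and 450 and 372 without the filter on dim probes. Il1b rose at least 62.8-fold. Nos2 rose 7.25-fold (log2 2.86 ± 0.19), Tnf 6.32-fold (log2 2.66 ± 0.13) and Ptgs2 3.24-fold (log2 1.70 ± 0.22). Hmox1 rose 3.52-fold, with log2 1.85 after the spatial correction. Actb did not pass (log2 -0.62, adjusted p = 0.1), and was at 0.02 with the normexp background correction. Cfb, a complement factor, rose 122-fold, Saa3, an acute-phase protein, 119-fold, Gbp2, an interferon-induced GTPase, 108-fold and Ccl5 94.4-fold. Unc93a, a membrane protein, rose at least 37.1-fold, Batf, a transcription factor of activated leukocytes, at least 43.2-fold and Slamf7 at least 42.2-fold.

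The largest falls after LPS, besides Arg1, follow. Il1r2, the decoy receptor of interleukin 1, fell at least 12-fold. Ccl24, an eosinophil attractant, fell 15.1-fold (log2 -3.91 ± 0.35). Apold1, a vascular stress gene, fell 21.8-fold and Cd2, an adhesion molecule, 16.6-fold. Sema4g, a semaphorin, Fxyd4, an ion pump regulator, and Cers4, a ceramide synthase, fell at least 10.5-fold (6.82-fold with control replicate 2 alone), 12.3-fold and 9.18-fold. F13a1, a clotting factor made by macrophages, fell at least 6.34-fold and Pianp at least 4.32-fold. Their spots were masked on control replicate 1, whose values alone give 2.42-fold and 2.73-fold, against 16.6-fold and 6.83-fold from control replicate 2. F13a1 passed in 2 and Pianp in 6 of the 8 fits without 1 array, and both passed after the correction too (adjusted p = 0.0017 and 9.2e-05).

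Interferon-stimulated genes rose broadly with LPS. Of 43 measured, 30 rose, none fell and 13 did not pass; adjusted over the list alone, 36 rose. The median was 1.93 (adjusted p = 1.4e-23; adjusted p = 0.11 with an estimated correlation). Gbp3, a relative of Gbp2, rose 26.3-fold. Oasl2 and Ifit3, both antiviral, rose 39.0-fold and 28.7-fold, but their spots were masked on control replicate 1 and the corrected log2 values were 3.43 and 4.78. Cytokines and inflammatory mediators had a median of 2.18 (adjusted p = 1.8e-11; adjusted p = 0.11 with an estimated correlation). Of 22 measured, 13 rose and 9 did not pass; adjusted over the list alone, 13 rose and 1 fell. The median was 0.90 without the filter on dim probes and 1.38 with probes above background on all arrays, and the list passed in both.

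Chemokines and NF-kB genes followed. Of 14 chemokines, 7 rose, 1 fell and 6 did not pass; adjusted over the list alone, 7 rose and 2 fell (median 1.57, adjusted p = 9e-05; adjusted p = 0.11 with an estimated correlation). The chemokine median was 0.64 with the normexp background correction, 0.28 with probes above background on all arrays and 0.19 without the filter on dim probes, and the list passed in each. Cxcl10, an interferon-induced T cell attractant, rose 55.2-fold, Ccl12 10.1-fold and Ccl8, a monocyte attractant, at least 2.95-fold. In the NF-kB pathway list, 13 of 26 rose and 13 did not pass; adjusted over the list alone, 18 rose and 1 fell (median 1.15, adjusted p = 1.8e-11; adjusted p = 0.11 with an estimated correlation). Traf1 rose 36.9-fold and Nfkbiz, an atypical NF-kB inhibitor, 10.6-fold. Bcl3, a related co-regulator, and Sod2, the mitochondrial superoxide dismutase, lay on spots masked on control replicate 1 and had corrected log2 values of 3.49 and 2.39.

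Glycolysis and hypoxia genes had the lowest median after LPS among lists that passed. Of 26 measured, 13 fell, 2 rose and 11 did not pass; adjusted over the list alone, 14 fell and 2 rose. The median was -0.94 (adjusted p = 9e-05; adjusted p = 0.11 with an estimated correlation), and -0.31 with the normexp background correction. Bnip3, a mitophagy receptor induced by hypoxia, fell 10.5-fold (log2 -3.39, but -2.77 without control replicate 1 and -2.81 after the spatial correction), Ndrg1 6.16-fold and Egln1 5.46-fold. Mitosis genes had a median of -0.49 (adjusted p = 0.0079; adjusted p = 0.37 with an estimated correlation), with 6 of 32 lower and 26 not passed, or 10 lower adjusted over the list alone. Without control replicate 2 they did not pass (adjusted p = 0.34). Kif20a, Cdc20 and Ube2c fell 2.21-fold, 2.15-fold and 2.11-fold. Oxidative phosphorylation genes had a median of -0.43 (adjusted p = 0.018; adjusted p = 0.16 with an estimated correlation), with 3 of 28 lower, 1 higher and 24 not passed; adjusted over the list alone, 6 fell and 1 rose. They too did not pass without control replicate 2 (adjusted p = 0.14), under quantile normalization (median -0.23) or with the normexp background correction (median -0.24). Cox7b and Cox5b, subunits of the terminal oxidase, fell 1.72-fold and 1.62-fold.

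Lists of stress and antioxidant genes were higher after LPS. In the NRF2 and antioxidant list, 11 of 31 rose and 20 did not pass; adjusted over the list alone, 14 rose and 1 fell (median 0.48, adjusted p = 0.00018; adjusted p = 0.11 with an estimated correlation). Slc7a11, the cystine transporter, rose 15-fold, Gclm, a subunit that makes glutathione, 3.03-fold, and Txnrd1, a thioredoxin reductase on a masked spot, had a corrected log2 of 1.56. In the integrated stress response list, 8 of 22 rose, 2 fell and 12 did not pass; adjusted over the list alone, 9 rose and 3 fell (median 0.48, adjusted p = 0.0085; adjusted p = 0.32 with an estimated correlation). Without control replicate 2 it did not pass (median 0.21, adjusted p = 0.18), and without the filter on dim probes its median was 0.19. Ddit3 rose 12.2-fold and Trib3 4.39-fold. In the p53 targets list, 7 of 20 rose, 1 fell and 12 did not pass; adjusted over the list alone, 7 rose and 5 fell (median 0.47, adjusted p = 0.0086; adjusted p = 0.32 with an estimated correlation). The p53 median was -0.01 with the normexp background correction and 0.19 without both arrays marked for evaluation, and the list passed in neither. The median was 0.20 after the spatial correction (adjusted p = 0.026 in camera) and 0.19 without control replicate 1. Fas, a death receptor, rose 22.4-fold and Gdf15, a stress cytokine, 7.35-fold.

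After LPS 4 further lists passed. Antigen presentation genes had a median of 0.73 (adjusted p = 2e-04; adjusted p = 0.31 with an estimated correlation), with 8 of 20 higher and 12 not passed, and 8 higher adjusted over the list alone. The median was 0.34 after the spatial correction and 0.38 without control replicate 1, and the list passed in both. Tap1 and Tapbp, which load peptides, rose 3.76-fold and 3.17-fold. Lysosome genes had a median of 0.29 (adjusted p = 0.0072; adjusted p = 0.31 with an estimated correlation), with 4 of 30 higher and 26 not passed, or 6 adjusted over the list alone; the median was 0.19 after the spatial correction. Lipa, the acid lipase, rose 1.64-fold. Apoptosis regulators had a median of 0.24 (adjusted p = 0.044; adjusted p = 0.32 with an estimated correlation), with 5 of 24 higher and 19 not passed; adjusted over the list alone, 6 rose and 3 fell. They did not pass after the spatial correction (median 0.08, adjusted p = 0.13), without control replicate 1 (median 0.08, adjusted p = 0.16) or without either HF array (adjusted p = 0.05). Casp4, an inflammatory caspase, rose 5.96-fold. Alternative activation genes had a median of -0.41 (adjusted p = 0.044; adjusted p = 0.32 with an estimated correlation), with 8 of 17 lower, 1 higher and 8 not passed; adjusted over the list alone, 8 fell and 2 rose. They did not pass without control replicate 2 (median -0.58, adjusted p = 0.48) or either HF array (adjusted p = 0.08). Egr2 fell 8.91-fold (log2 -3.15, but -2.45 without control replicate 1 and -2.55 after the spatial correction), while Msr1 rose 8.37-fold. The other 13 lists did not pass, among them microglial identity, where Cx3cr1 fell at least 4.50-fold and Gpr84, a fatty acid receptor of activated microglia, rose 3.29-fold.

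For LPS minus control, 184 and 175 genes passed without LPS replicate 1 and 2, 4570 and 11823 without control replicate 1 and 2, 1112 without either HF array, and 1109 without either LPS+HF array. Of 104 named genes that passed, 36 did so in all 8 of these fits, among them Marco, Lcn2, Il6, Arg1, Il1b, Nos2, Tnf and Cxcl10. In simulated data with the group spreads of these arrays, 74.4% of 4-fold and 23.2% of 2-fold changes were found over 22443 genes. However, 34.3% of the calls for this comparison were false, against 5.19% with equal spreads and 6% with those after the spatial correction. These shares come from 200 changed genes and need not hold for the real calls.

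HF minus control asked what HF did to unstimulated cells. Rtp4, an interferon-stimulated chaperone, fell 20.5-fold (log2 -4.36 ± 0.24 SE, 2 arrays per group, adjusted p = 0.0069). Ifi44 fell 16-fold (log2 -4.00 ± 0.34, adjusted p = 0.018) and Isg15 6.89-fold (log2 -2.78 ± 0.29, adjusted p = 0.023). Arg1 fell 21.7-fold (log2 -4.44 ± 0.42, adjusted p = 0.021), and the complement gene C1qc fell 5.53-fold (log2 -2.47 ± 0.15, adjusted p = 0.0084).

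With HF alone 198 genes passed, 32 higher and 166 lower. The split was 45 higher and 108 lower under quantile normalization, 1036 and 1282 after the spatial correction, and 0 and 8 with the normexp background correction. None of the inflammatory genes followed throughout passed before the spatial correction. Nos2 was at log2 -1.08 (adjusted p = 0.081) and Ptgs2 at -1.15 (adjusted p = 0.09), but both passed after it (-1.06, adjusted p = 0.016, and -0.96, adjusted p = 0.021). The others were Tnf at 0.01 (adjusted p = 0.98), Hmox1 at -0.14 (adjusted p = 0.63; -0.24 after the spatial correction) and Actb at -0.67 (adjusted p = 0.17). Il6 and Il1b were below background on both control arrays, with adjusted p = 0.5 and 0.92. Csta2, a cysteine protease inhibitor, fell 12.1-fold (log2 -3.60 ± 0.14, adjusted p = 0.0032), and its relatives Cstdc4 and Cstdc5 fell 13.6-fold and 14.3-fold. Prss46 fell at least 14.6-fold, Krt23, a keratin, at least 6.16-fold and Ifi211 13.3-fold. Il7r, the interleukin 7 receptor, fell at least 11.6-fold, and passed after the spatial correction that masked its spot (adjusted p = 0.019).

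The largest rises with HF alone sat close together on the array surface. Olfr1317, an odorant receptor, rose at least 5.67-fold, Cd55, a complement inhibitor, at least 5.15-fold (3.43-fold with HF replicate 1 alone), Ccnjl, a cyclin-like gene, at least 2.93-fold, Cfap206, a cilium gene, at least 2.69-fold and Gabrq, a GABA receptor subunit, at least 1.54-fold. These 5 belong to 25 probes that were bright on both HF arrays and dim on the 6 others, all within the first 70 of 384 spot rows. Olfr810, another odorant receptor in the same rows, rose at least 6.17-fold. Of the 32 higher genes, 22 lay in those rows (68.8%), against 19.9% of the 166 lower genes. However, 15 of the 32 belong to the 25 probes, and the limit of 70 rows was chosen after seeing those. The contrast is thus partly fixed in advance. Lbp, which rose 3.88-fold, also lay in those rows (row 35). Outside them, Prss16, a thymic protease, rose 3.25-fold and Wnt10a, a secreted signalling protein in row 72, 2.93-fold. Tyro3, a receptor for dying cells, rose 3.23-fold, but another of its probes moved the other way.

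The interferon-stimulated list was also lower with HF alone. Of 43 measured, 10 fell, none rose and 33 did not pass; adjusted over the list alone, 25 fell. The median was -1.13 (adjusted p = 1.6e-14; adjusted p = 0.29 with an estimated correlation), and -0.48 with the normexp background correction. Ifit3 fell at least 4.50-fold and passed after the spatial correction (adjusted p = 0.012). Mitosis genes had a median of 0.58 (adjusted p = 1.3e-10; adjusted p = 0.29 with an estimated correlation); none of 32 passed over all genes, and 11 rose adjusted over the list alone. Birc5, an inhibitor of cell death in dividing cells, and Hmmr, a spindle protein, had values of 1.71 and 1.57, but 0.36 and 0.38 after the spatial correction. DNA replication genes had a median of 0.44 (adjusted p = 9.5e-06; adjusted p = 0.29 with an estimated correlation), with 31 not passed and 2 higher adjusted over the list alone; the median was 0.29 after the spatial correction and 0.27 with the normexp background correction. Mcm4, a replicative helicase subunit, was at 2.20 and, after the correction, at 0.48.

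The microglial identity list was lower with HF alone. Of 28 measured, 5 fell, none rose and 23 did not pass; adjusted over the list alone, 10 fell. The median was -0.32 (adjusted p = 0.00028; adjusted p = 0.29 with an estimated correlation). The list did not pass without control replicate 2 (adjusted p = 0.088) or with the normexp background correction (adjusted p = 0.055). C1qb fell 2.81-fold. C1qa and Aif1, a calcium-binding microglial marker, were masked on control replicate 1. C1qa fell at least 2.11-fold with the unmasked control replicate 2 alone, and passed after the correction (adjusted p = 0.015) but in 2 of the 8 fits without 1 array, and Aif1 had a corrected log2 of -1.35. In the integrated stress response list 2 of 22 fell and 20 did not pass; adjusted over the list alone, 9 fell (median -0.44, adjusted p = 0.00038; adjusted p = 0.29 with an estimated correlation). Trib3 fell 2.49-fold and Chac1, which degrades glutathione, 2.05-fold, but Chac1 did not pass after the spatial correction (adjusted p = 0.099).

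Cholesterol synthesis genes had a median of -0.33 with HF alone (adjusted p = 0.00049; adjusted p = 0.29 with an estimated correlation). None of 25 passed over all genes, and 4 fell adjusted over the list alone. The list median was -0.53 after the spatial correction and -0.55 without HF replicate 2, and the list did not pass without control replicate 2 (adjusted p = 0.088). Fdps was at log2 -1.60 (adjusted p = 0.053) and Msmo1, a sterol oxidase, at -1.38 (adjusted p = 0.18; -0.69 without control replicate 1). Both passed after the spatial correction (-1.32, adjusted p = 0.0041, and -1.05, adjusted p = 0.044). Cytokines and inflammatory mediators had a median of -0.29 (adjusted p = 0.048; adjusted p = 0.49 with an estimated correlation), with 2 of 22 lower and 20 not passed, or 4 lower adjusted over the list alone. They did not pass after the spatial correction (median -0.20, adjusted p = 0.056), without control replicate 2 (adjusted p = 0.36), with the normexp background correction (adjusted p = 0.14), or under either other filter on dim probes (medians -0.42 and -0.18). Il1rn and Tnfsf15, a ligand of the tumour necrosis factor family, fell at least 2.48-fold and 1.55-fold. The other 20 lists did not pass. Among their members Cxcl10 fell 3.96-fold, Msr1 at least 3.72-fold, Mrc1, the mannose receptor, 3.41-fold and Fabp4 3.93-fold, while Nfkbia rose 2.01-fold.

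For HF minus control, 10 and 37 genes passed without HF replicate 1 and 2, 511 and 10169 without control replicate 1 and 2, 11 without either LPS array, and 26 without either LPS+HF array. Of 39 named genes that passed, Csta2, Cstdc4, Olfr1317 and Cfap206 did so in all 8 of these fits. In simulated data with the group spreads of these arrays, 76.1% of 4-fold and 28.4% of 2-fold changes were found over 22443 genes. However, 45.6% of the calls for this comparison were false, against 6.04% with equal spreads and 12.2% with those after the spatial correction. These shares come from 200 changed genes and need not hold for the real calls.

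**Figure D3:**
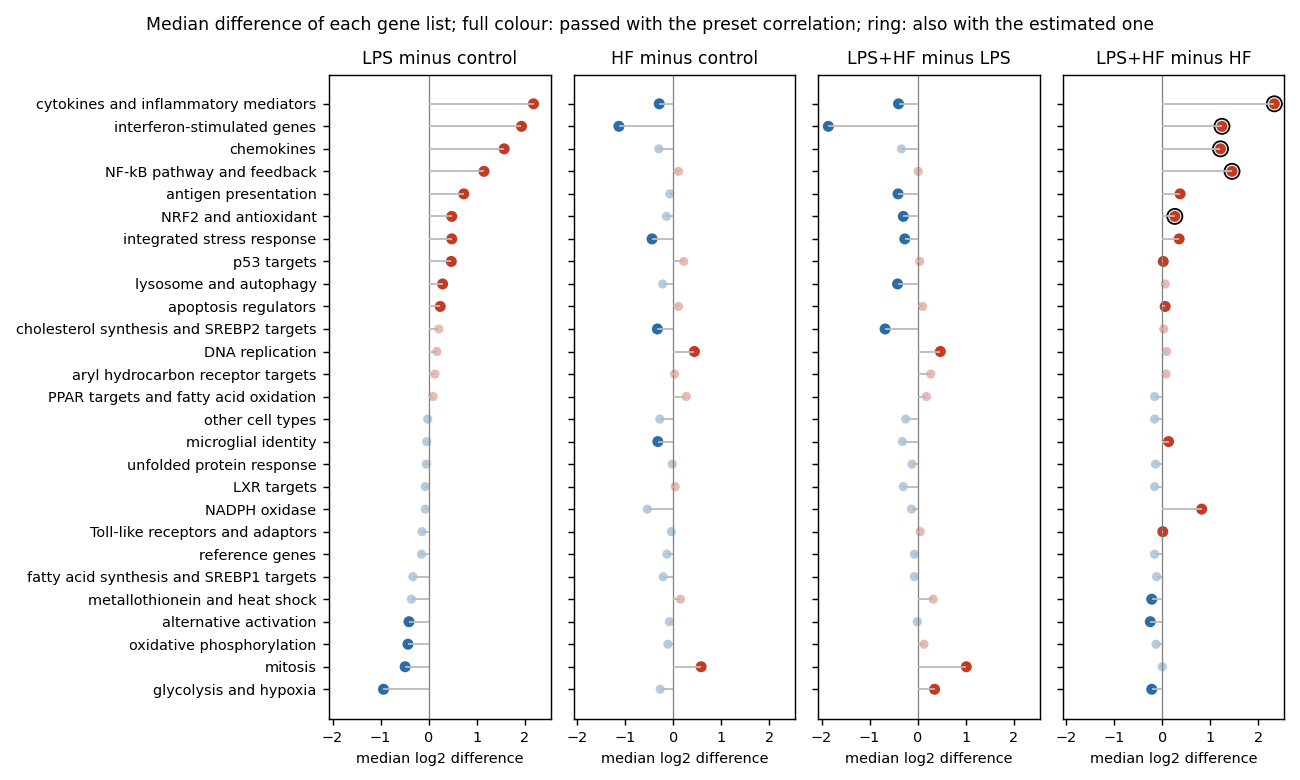
Median log2 difference of each gene list in 4 comparisons, with pale dots for lists that did not pass and rings for lists that also passed with an estimated correlation. Interferon-stimulated genes lie at -1.13 and -1.86 in the comparisons of HF, and at 1.93 and 1.24 in those of LPS.

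Genes that differed with HF overlapped between cells without and with LPS. The comparisons HF minus control and LPS+HF minus LPS share no array, but in both, HF and slide row cannot be told apart. Of 166 genes lower in the first and 732 lower in the second, 102 were the same, where independence would give 5.41. Of 32 and 672 higher genes, 7 were the same, where independence would give 0.957. In opposite directions, 2 were lower then higher and 0 higher then lower, where independence would give 4.97 and 1.04. Across the 22460 genes, which are not independent replicates, the differences had a Pearson r of 0.387 and a Spearman rho of 0.397. Leaving out 1 array gave r from 0.264, without control replicate 2, to 0.436, without control replicate 1, and rho from 0.266 to 0.472, without the same arrays.

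LPS+HF minus HF asked what LPS did in cells that also received HF. Marco rose 80.5-fold (log2 6.33 ± 0.13 SE, 2 arrays per group, adjusted p = 1e-04). Tnf rose 14.8-fold (log2 3.88 ± 0.13, adjusted p = 0.00039) and Cxcl10 53.6-fold (log2 5.74 ± 0.15, adjusted p = 0.00021). Il6 rose at least 5.95-fold and Il1b 13.6-fold (log2 3.76 ± 0.25, adjusted p = 0.003).

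In that comparison 287 genes passed, 203 higher and 84 lower. The split was 69 higher and 5 lower with the normexp background correction, and 717 and 432 after the spatial correction. Batf rose 146-fold, Saa3 73.4-fold, Lcn2 65.8-fold, Saa1, an acute-phase protein, 48.1-fold, Ccl5 40.2-fold and Vnn3, a pantetheinase, 39.7-fold. Cxcl2 rose at least 14.0-fold and Zfp811, a zinc finger gene, at least 13.3-fold. Nos2 rose 5.82-fold and Ptgs2 6.88-fold. Hmox1 did not pass (log2 0.26, adjusted p = 0.81; 0.33 after the spatial correction), nor did Actb (log2 -0.28, adjusted p = 0.83). Arg1 fell 28.7-fold (log2 -4.84). It ranged from -5.52 to -4.16 when 1 array was left out and passed in 6 of 8 such fits, with adjusted p = 0.065 without HF replicate 1. Ccl24 fell 6.57-fold and Gpr183, an oxysterol receptor, 6.52-fold. Kif26a, an atypical kinesin, fell at least 2.45-fold. Olfr1317, Cd55, Ccnjl, Cfap206, Gabrq and Ric3, an acetylcholine receptor chaperone, fell at least 6.11-fold, 5.55-fold, 3.16-fold, 2.90-fold, 1.66-fold and 2.65-fold. With HF replicate 1 alone Cd55 fell at least 3.70-fold and Ric3 at least 1.48-fold, and they passed in 6 and 4 of the 8 fits without 1 array. All 6 belong to the clustered probes bright on both HF arrays.

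LPS still raised the inflammatory lists in cells with HF, and 5 lists passed with an estimated correlation too. Cytokines and inflammatory mediators had 12 of 22 higher and 10 not passed, or 15 adjusted over the list alone (median 2.33, adjusted p = 7.2e-33; adjusted p = 0.037 with an estimated correlation). That median was 1.44 with the normexp background correction, 1.46 without the filter on dim probes and 1.47 with probes above background on all arrays. Il1a, the cytokine interleukin 1 alpha, rose at least 18.1-fold and Acod1 27.6-fold. Chemokines had 6 of 14 higher and 8 not passed, or 8 adjusted over the list alone (median 1.21, adjusted p = 4.2e-11; adjusted p = 0.037 with an estimated correlation). Their median was 0.66 with the normexp background correction and -0.04 over all 21 members without the filter on dim probes. Ccl9 rose 3.99-fold. Interferon-stimulated genes had 14 of 43 higher and 29 not passed, or 30 adjusted over the list alone (median 1.24, adjusted p = 8.5e-42; adjusted p = 0.037 with an estimated correlation). Gbp2 rose 24.2-fold and Rsad2, an antiviral enzyme, 14.7-fold. NF-kB genes had 12 of 26 higher and 14 not passed; adjusted over the list alone, 18 rose and 1 fell (median 1.45, adjusted p = 2.3e-29; adjusted p = 0.02 with an estimated correlation). Traf1 rose 13.3-fold, Nfkbiz 9-fold and Nfkbia 6.88-fold. The NRF2 and antioxidant list had 2 of 31 higher and 29 not passed, or 8 adjusted over the list alone (median 0.26, adjusted p = 9.6e-07; adjusted p = 0.037 with an estimated correlation). That median was 0.16 without LPS+HF replicate 1 and 0.44 without LPS+HF replicate 2. Slc7a11 rose 17.9-fold.

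Another 10 lists passed in LPS+HF minus HF with the preset correlation alone, and their adjusted p with an estimated correlation lay between 0.14 and 0.25. Integrated stress response genes had a median of 0.35, antigen presentation 0.37, NADPH oxidase 0.82, microglial identity 0.13, p53 targets 0.02, apoptosis regulators 0.06 and Toll-like receptors 0.01, which became -0.05 with the normexp background correction. Glycolysis had a median of -0.22, as did metallothionein and heat shock genes, and alternative activation -0.25. Toll-like receptors did not pass after the spatial correction (median -0.02, adjusted p = 0.067), without either control array (adjusted p = 0.09) or without LPS+HF replicate 1 (median -0.07, adjusted p = 0.069). Alternative activation and glycolysis did not pass without HF replicate 2 (adjusted p = 0.28 and 0.13) or LPS+HF replicate 2 (adjusted p = 0.1 for both). Metallothionein and heat shock did not pass without HF replicate 2 or LPS+HF replicate 1 (adjusted p = 0.06 and 0.057). Leaving out 1 array of HF or LPS+HF put microglial identity between 0.04, without LPS+HF replicate 1, where it did not pass (adjusted p = 0.051), and 0.22. The ranges were 0 to 0.17 for p53 targets and -0.01 to 0.16 for apoptosis regulators, and NADPH oxidase was at 0.50 without HF replicate 1. With the normexp background correction glycolysis (-0.14) and metallothionein and heat shock (-0.15) did not pass either, and alternative activation was at -0.14 and the integrated stress response at 0.23. Chac1 rose 3.93-fold, Cd40, a co-stimulatory receptor, 3.76-fold, Cybb, the catalytic oxidase subunit, 4.72-fold, Gpr84 5.12-fold, Fas 15.8-fold, Casp4 3.67-fold and Tlr2, a receptor for bacterial lipoproteins, 3.58-fold. Ndrg1 fell 1.97-fold. The other 12 lists did not pass.

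For LPS+HF minus HF, 76 and 123 genes passed without HF replicate 1 and 2, 56 and 104 without LPS+HF replicate 1 and 2, 133 without either LPS array, and 887 without either control array. Of 57 named genes that passed, 24 did so in all 8 of these fits, among them Marco, Tnf, Il6, Il1b, Cxcl10, Saa3 and Cxcl2. In simulated data with the group spreads of these arrays, 69.0% of 4-fold and 12.6% of 2-fold changes were found over 22443 genes, with 1.81% of the calls for this comparison false.

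The response to LPS in cells with HF was set against that in cells without it as a slope across genes, where 1 would mean an equal response. The slope was 0.697 over 43 interferon-stimulated genes, 0.794 over 22 cytokines and inflammatory mediators and 0.883 over 14 chemokines. After the spatial correction the interferon slope was 0.756, and without control replicate 1 it was 0.755. For cytokines the median response was 2.33 log2 with HF and 2.18 without it. Of those 22 genes 63.6% responded less with HF, or 50% after the spatial correction. Over the 2502 genes that passed in LPS minus control the slope was 0.489. Choosing genes on 1 of the 2 responses lowers that slope: simulated data with equal responses gave a mean of 0.848, and a response of 0.5 gave 0.423, each over 22443 genes. The simulated responses were the measured values of the genes that passed, and 0 for all others. Those values were themselves chosen by passing, so the simulation may understate how far the choice lowers the slope. The slope of 0.489 therefore does not give the share of the response kept with HF. When 1 array was left out, the genes were chosen again, so the slopes cover different sets. They were 0.191 without control replicate 2, where only the uneven control array remained, and 0.642 without LPS replicate 2. The ranges for the lists were 0.594 to 0.762, 0.771 to 0.818 and 0.840 to 0.926. Of the genes that passed, 179 were higher in both LPS comparisons, out of 1078 and 203, and 48 were lower in both, out of 1424 and 84, where independence would give 9.74 and 5.33. In opposite directions, 0 were higher then lower and 2 lower then higher, where independence would give 4.03 and 12.9. Both comparisons use the same pooled spread per gene, so these expected counts are no exact reference either.

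**Figure D4:**
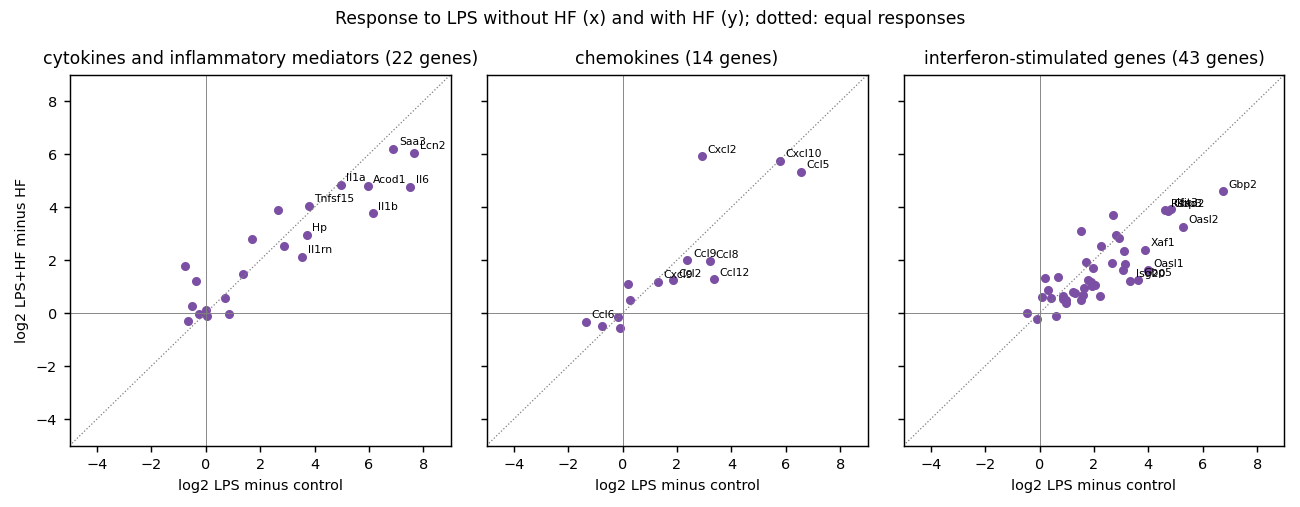
Response of list members to LPS without HF (x axis) and with HF (y axis), both as log2 differences of group means, with a dotted line for equal responses. Interferon-stimulated genes lie mostly below the line, with a slope of 0.697; genes below background without LPS, such as Il6 and Cxcl2, are drawn as measured and have no exact response.

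The interaction tested whether the change with HF differed between cells with and without LPS. Sfpq was 2.46 ± 0.19 log2 higher than the separate changes add up to (SE, 2 arrays per group, adjusted p = 0.041). The other named genes that passed were below background in at least 1 group, so the sizes of their interactions are not known. Cx3cr1 (2.98, adjusted p = 0.041) was below background on the LPS arrays. With HF it rose at least 3.08-fold in cells with LPS and fell in cells without LPS (log2 -1.22, adjusted p = 0.029). Slfn4 and Mirt2 (-3.53 and -4.02, adjusted p = 0.041 for both) were above background on the LPS arrays alone. Olfr1317 (-4.56, adjusted p = 0.039) and Cfap206 (-3.47, adjusted p = 0.041) belong to the clustered probes bright on the HF arrays alone.

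In total 12 genes passed the interaction, 3 higher and 9 lower, or 430 and 303 after the spatial correction; 6 of the 12 have no approved-style symbol. Il6 (-2.75, adjusted p = 0.086), Il1b (-2.38, adjusted p = 0.14), Hmox1 (-1.56, adjusted p = 0.14), Tnf (1.22, adjusted p = 0.13), Ptgs2 (1.09, adjusted p = 0.29), Nos2 (-0.32, adjusted p = 0.67) and Actb (0.34, adjusted p = 0.65) did not pass. Neither did Cxcl2 (3.01, adjusted p = 0.097) or Ddit3 (-3.23, adjusted p = 0.071). Il6, Il1b and Cxcl2 were below background on the control arrays, so their values are not exact. After the spatial correction Il6, Il1b, Hmox1, Tnf, Cxcl2 and Ddit3 passed (adjusted p = 0.0099, 0.017, 0.041, 0.02, 0.02 and 0.0077), with Hmox1 at -1.52.

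Among the lists, 7 passed the interaction with the preset correlation. Interferon-stimulated genes had a median of -0.69 (adjusted p = 0.00031; adjusted p = 0.64 with an estimated correlation); of 43 none passed, and adjusted over the list alone 3 were lower and 1 higher. Glycolysis and hypoxia genes had a median of 0.74 (adjusted p = 2e-04; adjusted p = 0.2 with an estimated correlation); of 26 none passed, and adjusted over the list alone 10 were higher and 2 lower. Bnip3 was at 2.71 and Egln1 at 1.92, and both passed after the spatial correction (2.22, adjusted p = 0.0077, and 1.69, adjusted p = 0.0091). Mitosis genes had a median of 0.52 (adjusted p = 0.00049; adjusted p = 0.58 with an estimated correlation), and 1 of 32 was higher adjusted over the list alone. Microglial identity (0.19, adjusted p = 0.046), NADPH oxidase (0.51, adjusted p = 0.034), lysosome and autophagy (-0.22, adjusted p = 0.034) and oxidative phosphorylation (0.32, adjusted p = 0.04) also passed, with adjusted p between 0.57 and 0.78 with an estimated correlation. Without control replicate 1 the median was -0.41 for interferon-stimulated genes and 0.18 for oxidative phosphorylation, and both lists passed. Microglial identity (0.15, adjusted p = 0.062) and NADPH oxidase (0.25, adjusted p = 0.2) did not pass there, and NADPH oxidase did not after the spatial correction (0.28, adjusted p = 0.096). With the normexp background correction glycolysis was at 0.24, and microglial identity, NADPH oxidase (0.24) and oxidative phosphorylation (0.16) did not pass, nor did these 3 under quantile normalization. Without control replicate 2 only interferon-stimulated genes passed of the 7. Oxidative phosphorylation and lysosome also did not pass without LPS replicate 2 (adjusted p = 0.09 and 0.051) or LPS+HF replicate 2 (adjusted p = 0.073 and 0.14). Without HF replicate 1 microglial identity, oxidative phosphorylation (adjusted p = 0.13 for both) and NADPH oxidase (adjusted p = 0.077) did not pass, and glycolysis was at 0.49. Lysosome was at -0.07 without HF replicate 2 (adjusted p = 0.1). Microglial identity also did not pass without LPS replicate 2 or LPS+HF replicate 1 (adjusted p = 0.09 and 0.1). The other 20 lists did not pass.

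Over the 5 comparisons, 7 of the 27 lists passed nowhere: unfolded protein response, fatty acid synthesis, LXR targets, PPAR targets, aryl hydrocarbon receptor targets, other cell types and reference genes. The median, the mean and the direction of the test differed in sign only in lists that did not pass. In LPS minus control, Toll-like receptors had a median of -0.14 and a test directed upward, and fatty acid synthesis had a median of -0.33 and a mean of 0.12 (adjusted p = 0.7 for both).

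For the interaction, 55 and 7934 genes passed without control replicate 1 and 2, and 0 in limma without any 1 of the 6 other arrays, with 1369 to 1925 at an unadjusted p under 0.05. In simulated data with the group spreads of these arrays, 29.8% of 4-fold and 0.6% of 2-fold interactions were found over 22443 genes, and 14.1% of the calls were false.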

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

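The tests of a lasting culture difference, of the position of probes on the array, of the comparison without control arrays, and of the slide row were chosen after the results were seen.

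The change with HF differed between cells with and without LPS for 12 genes, by limma's interaction test at an adjusted p under 0.05. The named ones were Cx3cr1 (2.98), Sfpq (2.46), Olfr1317 (-4.56), Mirt2 (-4.02), Slfn4 (-3.53) and Cfap206 (-3.47), as log2 interactions. Of the 12 genes, 4 are probes of the clustered set bright on both HF arrays, Olfr1317 and Cfap206 among them. All named genes but Sfpq were below background in at least 1 group, so the sizes of their interactions are not known: Cx3cr1 on the LPS arrays, and Slfn4 and Mirt2 on all but the LPS arrays. After the spatial correction 733 genes passed, and without control replicate 1 or 2 the count was 55 or 7934, and without any 1 of the other 6 arrays it was 0 in limma, with 1369 to 1925 genes at an unadjusted p under 0.05.

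Of the 27 lists, 7 also differed by the camera test of the interaction with the preset correlation. Their medians were -0.69 for interferon-stimulated genes, 0.19 for microglial identity, 0.51 for NADPH oxidase, -0.22 for lysosome and autophagy, 0.52 for mitosis, 0.74 for glycolysis and hypoxia, and 0.32 for oxidative phosphorylation. With an estimated correlation 0 passed in camera, and fry called 3. Without control replicate 1 the interferon-stimulated median was -0.41, and NADPH oxidase and microglial identity did not pass (0.25, adjusted p = 0.2, and 0.15, adjusted p = 0.062).

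The control arrays differed from each other more than the arrays of any other group, with an SD of 0.992 log2 over the genes against at most 0.488. A lasting difference between the control samples would have left the SD high after the spatial correction. It fell to 0.435, over the 18986 genes left after masking, against 0.389 in the next group. The larger SD lay where control replicate 1 was locally uneven. That is partly fixed in advance, since the uneven zone was defined by that array's deviation from arrays that included control replicate 2. The planned test of uneven hybridisation came out near its bound. Over the 12601 genes where control replicate 1 deviated locally by under 0.5 log2 the SD was 0.495, above the bound of 0.488 set before the test. Over the other 9859 genes it was 1.39. The excess of 0.0074 was smaller than its bootstrap SE of 0.011 (1000 draws), a spread added after the value was seen, so uneven hybridisation and another source cannot be told apart for the even zone.

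Of the probes kept, 25 were bright on both HF arrays and dim on the 6 others, and all lay in the first 70 of 384 rows of spots, a limit chosen after seeing them. RNA induced by HF would raise other probes of the same genes too, but 12 such probes of 7 genes had a median HF minus control of -0.29 log2, against 3.64 in the set. A local artefact at shared positions of both HF arrays is a candidate explanation: the median distance to the nearest probe of the set was 1.41 spots, against 25.1 for random sets and 8.25 in the closest of 10000. However, 286 kept probes within 3 spots of the set had a median HF minus control of 0.20 log2, against -0.06 over all kept probes, so most neighbouring spots moved little. The 72 probes bright on LPS arrays alone were at 13.9 spots, against 14.3 at random. In LPS+HF minus LPS the median of the set was -0.20.

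The interferon-stimulated list was lower with HF both without and with LPS in camera with the preset correlation. With an estimated correlation it passed in neither (adjusted p = 0.29 and 0.21). In LPS+HF minus LPS, an effect of brightness or scaling on all genes of like expression is argued against. There, 10000 lists matched on expression had medians no lower than -0.27 where this list had -1.86, and quantile normalization and median scaling gave -1.88 and -1.83. The planned test did not cover HF minus control. In that comparison matched lists had medians no lower than -0.33 where this list had -1.13, but it had -0.48 with the normexp background correction. Uneven hybridisation of control replicate 1 cannot account for the value of -1.86 either, since LPS+HF minus LPS uses no control array. The slide row stays open: 0 rows held arrays both with and without HF, so row and HF cannot be told apart. An effect of HF on interferon signalling may be the biological explanation, but it was not tested apart from the slide row.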

How the results depend on the processing

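The spatial correction, alone or with the replicate block, the array weights, and leaving out both arrays marked for evaluation were chosen after the data were seen. Counts below are genes past an adjusted p under 0.05 in limma, for LPS minus control, HF minus control, LPS+HF minus LPS, LPS+HF minus HF and the interaction, in that order, against 2502, 198, 1404, 287 and 12. Where a cause is not given, the cause was not tested.

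Median scaling, the authors' matrix, the mean over a gene's probes and single probes left every count within 1.5 times. Quantile normalization and probes above background on all arrays did so too except for the interaction, at 5 and at 0 (2330 at an unadjusted p under 0.05), as did the trended and robust variance, with 0 (2658). The normexp background correction gave 1046, 8, 232, 74 and 0 (1554 unadjusted). It starts from raw medians without the scanner's trend correction, so its counts do not single out the background step. The lowest local deviation of control replicate 1 was -6.81 log2 before the trend correction and -2.34 in the processed signals. Without a filter on dim probes, which adds genes near background to the adjustment, the counts were 822, 13, 168, 127 and 0 (2453 unadjusted). A 2-fold threshold gave 1523 for LPS minus control and 850 for LPS+HF minus LPS. Fits on only the arrays compared gave 67, 0 (1717 unadjusted) and 7397 for the first 3.

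The replicate block, which pairs arrays of the same number, gave 44 for HF minus control, 592 for LPS+HF minus LPS and 0 for the interaction (2354 unadjusted), with 1704 and 199 for the others. The correlation of replicate deviations between groups was 0.266 for control and HF, and between -0.0869 and 0.0489 for the other pairs of groups. After the spatial correction it was 0.00699 for control and HF, and between -0.112 and 0.0877 for the others.

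The spatial correction gave 6468, 2318, 6462, 1149 and 733, and shared 2447, 194, 1403, 287 and 12 genes with the counts above. With the replicate block it gave 5680, 1311, 5600, 836 and 110. Without both arrays marked for evaluation the counts were 4846, 174, 7397, 453 and 34. Array weights gave 159, 0 (1584 unadjusted), 8313, 994 and 0 (1849 unadjusted). The 2 arrays of a group got the same weight, 0.145 for both control arrays and 2.79 for both LPS arrays. Control replicate 1 was thus not weighted down apart from control replicate 2.

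Leaving out 1 array gave 175 (without LPS replicate 2) to 11823 (without control replicate 2) in LPS minus control, and 10 (without HF replicate 1) to 10169 (without control replicate 2) in HF minus control. In LPS+HF minus LPS it gave 0 (without LPS replicate 1 or 2; 2981 and 3115 unadjusted) to 6567 (without control replicate 1 or 2). In LPS+HF minus HF it gave 56 (without LPS+HF replicate 1) to 887 (without control replicate 1 or 2). In the interaction it gave 0 (without any LPS, HF or LPS+HF array; 1369 to 1925 unadjusted) to 7934 (without control replicate 2). A lone control array adds nothing to the pooled spread, so the difference between the control arrays no longer enters it.

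Of 288 calls of named genes, 285 held under median scaling, 254 under quantile normalization, 287 under the spatial correction, 195 under the replicate block, 143 without the filter and 135 with the normexp background correction. That correction reversed Canx, Ebp and Elovl6 in LPS minus control, to 0.39, 0.23 and 0.11 (adjusted p = 0.6, 0.72 and 0.85). Cd86 in HF minus control went from 0.64 to -0.78 under the spatial correction (adjusted p = 0.044). Fits on only the arrays compared, which cannot give the interaction, kept 159 of 282 calls of named genes. They kept 26 of 104 in LPS minus control and 0 of 39 in HF minus control. In LPS+HF minus LPS they kept 82 of 82, and in LPS+HF minus HF 51 of 57.

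With an estimated correlation camera called 0 lists in LPS minus control, HF minus control, LPS+HF minus LPS and the interaction, and 5 in LPS+HF minus HF, against 14, 7, 10, 7 and 15. Fry called 14 lists in HF minus control and 3 in the interaction. Leaving out 1 array gave 4 (without control replicate 2) to 10 (without HF replicate 2 or control replicate 1) lists in HF minus control and 1 (without control replicate 2) to 9 (without LPS+HF replicate 1) in the interaction, where leaving out LPS replicate 2 or HF replicate 1 gave 4. Of 53 list calls, 46 held under quantile normalization, 42 with the normexp background correction, 47 under the spatial correction and 37 without control replicate 2, with 0 reversed by the direction of camera's test.

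The slope of the LPS response over genes that passed, chosen again in each fit, was 0.191 to 0.642 when 1 array was left out. The lowest came without control replicate 2 and the highest without LPS replicate 2. For cytokines the slope was 0.777 under quantile normalization, 0.864 with probes above background on all arrays, and 0.771 to 0.818 with 1 array left out. For chemokines it was 0.774 with normexp, 0.798 without the filter, 0.813 with probes above background on all arrays, 0.856 without both marked arrays, and 0.840 to 0.926 with 1 array left out. For interferon-stimulated genes it was 0.5 with normexp and 0.594 to 0.762 with 1 array left out.

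The Pearson correlation of the HF differences was 0.327 with normexp, 0.335 under quantile normalization, 0.269 without the filter, 0.44 with probes above background on all arrays, 0.45 under the spatial correction, 0.477 without both marked arrays, and 0.264 to 0.436 with 1 array left out. Spearman's was 0.325 under quantile normalization, 0.311 without the filter, 0.472 under the spatial correction, 0.531 without both marked arrays, and 0.266 to 0.472 with 1 array left out. Both lowest values came without control replicate 2. A block for slide or scan was not run, since there was 1 of each.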
